A study of Homo sapiens with 36 samples.

How the data were processed

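Total RNA from the prostate cancer lines LNCaP, VCaP and CWR22Rv1 (CWR) was measured on an Illumina expression BeadChip, 36 arrays in all. Per the labels, cells were pretreated with enzalutamide or DMSO for 24 h and then treated with DMSO, enzalutamide, olaparib or both for 48 h. Each of the 12 groups of line and treatment had 3 arrays. The labels do not say whether the replicates were separate cultures, and they name no batch or slide. Concentrations are not stated.

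The deposited file of raw data holds probe signals as intensity, 47231 probes per array, without background subtraction or normalization as far as the values show. It holds no detection p-values, bead numbers or control probes. The deposited series matrix holds log2 values that the authors quantile normalized: every array has the same sorted values, and within each array they keep the rank order of the raw signals. The authors' software and any background step are not given in the sources used here.

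The comparisons used the raw signals. Probes were named through their Entrez gene ID in a RefSeq gene table (35672 probes), otherwise by the symbol in the file (8289), and 3270 probes without a symbol were left out. The background was to be taken from negative controls or detection p-values, which the files used here do not hold. It was instead estimated on each array from the mode of its log2 signal density, with the spread of the signals below the mode, a choice made after the signals were seen. With these values, signals were corrected by limma's normexp, an offset of 16 was added, and arrays were quantile normalized on the log2 scale. A probe was kept if its detection p, from a normal distribution with the same background, was under 0.05 on all 3 arrays of at least 1 group. That left 22249 probes of 16769 genes, each gene represented by its brightest kept probe on average. 4285 genes had over 1 kept probe, and these probes often differed: of 465 such genes with a called probe in ENZ+OLA vs DMSO, CWR, 422 also had a probe that was not called.

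VCaP OLA replicate 1 was dim. The 95th percentile of its signals was 159.8, against 1359 to 3471 on the other arrays. 21.8% of its probes were detected, against 43.1% to 49.2%, and its mean correlation with its own group was 0.899, against at least 0.974 in the other groups. It was kept in the main comparisons, as planned, and counts without it are printed beside them, with list means where the comparison holds it (17009 genes). All 36 arrays correlated most with arrays of their own line. ERG, read as a check of the line labels, averaged 5.15 to 6.21 (log2) in the VCaP groups and at most 4.56 in the others.

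A linear model with a mean per group was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, 24 residual degrees of freedom), without a replicate block. Within each line, 5 contrasts were tested, along with the departure of the combination from the sum of the 2 single effects on the log2 scale. Differences of a response between lines used a moderated F test of 2 contrasts. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Folds of genes below background in all arrays of 1 group were computed against the background level and are given as at least that size.

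19 gene lists, written from general knowledge before the data were examined, were tested with limma camera at a preset correlation of 0.01 and adjusted over all 285 tests, with an estimated correlation and fry beside it. They covered genes of androgen induction and repression, homologous recombination and Fanconi, other DNA repair, DNA replication and G1/S, G2/M and mitosis, p53 targets, interferon, cholesterol and fatty acid synthesis, ER stress and ATF4, heat shock, immediate-early and handling stress, and glucocorticoid induction. The others were neuroendocrine, basal epithelial, stromal and leukocyte markers and housekeeping genes. 94 tests passed, 65 of them also with an estimated correlation.

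Genes named in the text followed a rule set before the data were examined: for each comparison the 5 largest rises and falls past the threshold whose 3 arrays of each group did not overlap (for 3 against 3, 10% of genes do so by chance), without unnamed loci and pseudogenes; up to 4 members of each list past its threshold and any member past it the other way; and a panel of genes (KLK3, TMPRSS2, FKBP5, BRCA1, BRCA2, RAD54L, PARP1, CDKN1A, MKI67, MCM2 and 3 that are not reported here). For the departure from the sum and the differences between lines, these were the 5 smallest p-values and the panel. Some genes of the rule were left out for length.

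The steps were tested on simulated data with 50 genes changed at each of 4 folds in 1 comparison, enzalutamide against DMSO in LNCaP. With 36 arrays, 26% of genes changed by 1.5-fold, 44% by 2-fold, 68% by 3-fold and 72% by 4-fold were called, and among bright genes 57.1%, 75%, 100% and 100%. Of 113 calls, 7 were false, and 9 calls were made over 12 unchanged comparisons. With 35 arrays, 14 of 131 calls were false. Small changes of dim genes are largely missed.

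Results were also computed with quantile normalization without background correction, median scaling, the authors' series-matrix values, no detection filter, probes detected on all arrays, the mean of a gene's probes, each cell line alone, a trend with robust variance, a replicate block, and leaving out each array in turn. A slide block was not run, since the files name no slides. The 35 arrays, array quality weights, list tests of the departure from the sum and of line differences, list means over members with signal in either group, and a hypoxia-response list were added after the data were seen.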

Results

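Expression was compared in 3 prostate cancer cell lines, LNCaP, VCaP and CWR22Rv1 (CWR below), after vehicle (DMSO), the androgen receptor antagonist enzalutamide (ENZ), the PARP inhibitor olaparib (OLA) or both. In LNCaP, enzalutamide lowered most androgen-induced genes, olaparib raised p53 target genes and lowered cell division genes, and the combination held both changes with a larger fall of mitosis genes. In VCaP, enzalutamide changed part of the androgen-induced genes and lowered DNA replication genes, while few genes passed the threshold with olaparib. In CWR, 16 genes passed the threshold with enzalutamide, and olaparib raised p53 targets. A set of transcripts that passed with neither agent alone was lower with the combination, where a shift in RNA or labelling stays open.

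Values in brackets are log2 changes between group means with the moderated standard error (SE), n = 3 arrays per group unless stated, and adjusted p-values of genes are from limma. List results give how many measured members rose, fell or did not pass at an adjusted p of 0.05 over all genes, then the same 2 counts with p adjusted over the list alone where they differ, and the limma camera test of the whole list, adjusted over 19 lists and 15 comparisons except where stated. 1 array, VCaP OLA replicate 1, was much dimmer than the rest, and it widened the spread that all groups share. Counts are therefore given with 36 arrays and, beside them, with the 35 others, a comparison added after the signals were seen. The labels do not say that the 3 replicates of a group were separate cultures, so they may be technical.

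**Figure D1:**
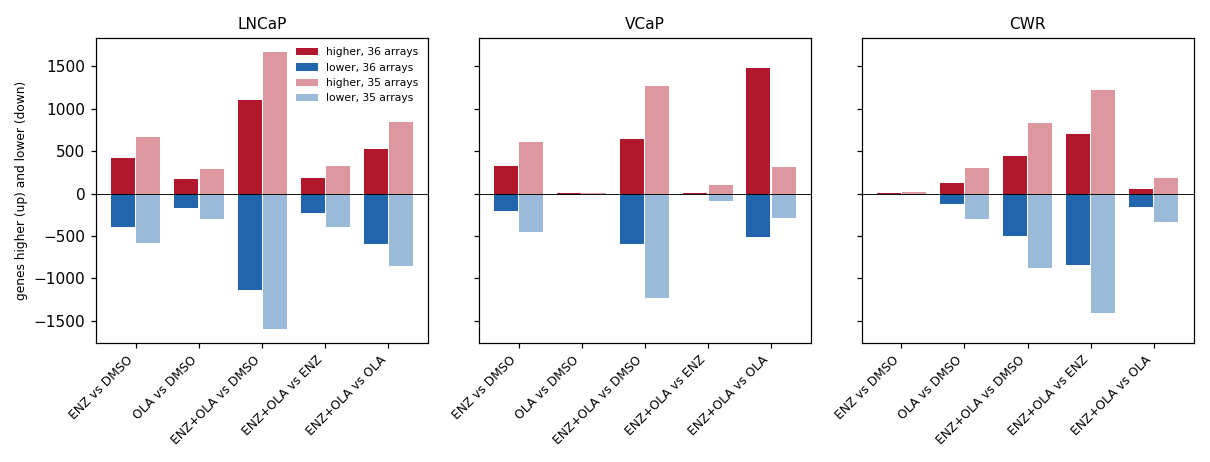
Genes higher and lower at an adjusted p under 0.05 (limma) in each comparison within a cell line, with all 36 arrays (dark) and with the 35 arrays other than the dim one (pale).

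In LNCaP, enzalutamide lowered the androgen-induced programme, with smaller falls in lipid synthesis and cell cycle genes and a rise of androgen-repressed genes. Against DMSO, 812 genes (422 higher, 390 lower) passed the threshold. With 35 arrays, 1254 genes (668 higher, 586 lower) did. With 36 arrays, 351 rose and 312 fell by at least 1.5-fold. The genes that rose most were OPRK1 (3.54, SE 0.18), LRRC31 (3.30, SE 0.15), KCNU1 (3.26, SE 0.21), DDC (3.13, SE 0.13) and IL1RN (3.03, SE 0.21). Those that fell most were HPGD (at least 14.0-fold lower), TARP (-4.11, SE 0.26), TRPM8 (-3.73, SE 0.18), ELOVL7 (-3.56, SE 0.26) and ADH1A (at least 9.17-fold lower).

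The androgen-induced list fell in LNCaP with enzalutamide (32 fell, 0 rose and 8 of 40 did not pass, 34 and 0 over the list alone, mean -1.72, camera adjusted p = 2.23e-89). Members included TMPRSS2 (-3.31, SE 0.13) and ADAM7 (at least 6.56-fold lower). In the fixed panel, KLK3 (-2.93, SE 0.35) and FKBP5 (-1.92, SE 0.13) fell as well. Androgen-repressed genes rose (5 rose, 0 fell and 5 of 10 did not pass, mean 0.91, camera adjusted p = 2.58e-08). Members included UGT2B15 (1.83, SE 0.28), UGT2B17 (1.56, SE 0.14) and UGT2B11 (1.17, SE 0.28). Glucocorticoid-induced genes, 3 of which are also in another list, fell (5 fell, 0 rose and 4 of 9 did not pass, 5 and 1 over the list alone, mean -0.69, camera adjusted p = 1.68e-06). Members included ZBTB16 (-2.21, SE 0.18) and SGK1 (-1.66, SE 0.33).

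Cholesterol synthesis genes fell with enzalutamide in LNCaP (8 fell, 1 rose and 13 of 22 did not pass, 14 and 1 over the list alone, mean -0.41, camera adjusted p = 1.90e-10). Members included INSIG1 (-0.94, SE 0.16), HMGCS1 (-0.84, SE 0.12), SQLE (-0.76, SE 0.16) and EBP (-0.72, SE 0.20), whereas TM7SF2 (0.73, SE 0.13) rose. Fatty acid synthesis genes fell (3 fell, 0 rose and 11 of 14 did not pass, 5 and 0 over the list alone, mean -0.52, camera adjusted p = 1.20e-05). Members included ELOVL5 (-1.84, SE 0.16) and FADS1 (-0.62, SE 0.15). DNA replication and G1/S genes fell (4 fell, 0 rose and 38 of 42 did not pass, mean -0.27, camera adjusted p = 3.07e-07). Members included POLE2 (-0.60, SE 0.14) and PRIM1 (-0.55, SE 0.13). So did G2/M and mitosis genes (2 fell, 0 rose and 35 of 37 did not pass, 11 and 0 over the list alone, mean -0.30, camera adjusted p = 3.70e-10). Members included CCNA2 (-0.65, SE 0.15) and KIF20A (-0.46, SE 0.13). Homologous recombination and Fanconi genes shifted down slightly (1 fell, 1 rose and 40 of 42 did not pass, mean -0.13, camera adjusted p = 0.0162, 0.291 with an estimated correlation). In that list RMI2 (-0.54, SE 0.13) fell and BARD1 (0.89, SE 0.22) rose. Interferon-stimulated genes rose (2 rose, 0 fell and 21 of 23 did not pass, mean 0.20, camera adjusted p = 0.0138, 0.291 with an estimated correlation). Members included BST2 (0.99, SE 0.19) and OASL (0.44, SE 0.11).

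Olaparib alone gave LNCaP a rise of p53 target genes and a fall of mitosis and DNA replication genes, without lowering androgen-induced genes. Against DMSO, 342 genes (170 higher, 172 lower) passed. With 35 arrays, 581 genes (283 higher, 298 lower) did. With 36 arrays, 139 rose and 139 fell by at least 1.5-fold. CEL (3.28, SE 0.30), TP53I3 (2.88, SE 0.24), SPATA18 (2.42, SE 0.15), FAXDC2 (2.38, SE 0.20) and CDKN1A (2.25, SE 0.15) rose most. TMEM45A (-2.32, SE 0.21), STC1 (-1.89, SE 0.24), LOX (-1.67, SE 0.17), PLOD2 (-1.65, SE 0.19) and TGM3 (-1.49, SE 0.26) fell most.

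The p53 target list rose in LNCaP with olaparib (18 rose, 0 fell and 13 of 31 did not pass, 25 and 0 over the list alone, mean 0.95, camera adjusted p = 1.89e-46). Members included FAS (1.71, SE 0.24). G2/M and mitosis genes fell (22 fell, 0 rose and 15 of 37 did not pass, 33 and 0 over the list alone, mean -0.59, camera adjusted p = 8.88e-42). Members included PLK1 (-1.05, SE 0.28), CCNA2 (-0.94, SE 0.15), NDC80 (-0.92, SE 0.15) and BUB1 (-0.88, SE 0.18). DNA replication and G1/S genes fell (12 fell, 0 rose and 30 of 42 did not pass, 20 and 0 over the list alone, mean -0.38, camera adjusted p = 7.17e-18). Members included CCNE2 (-0.86, SE 0.18), POLE2 (-0.85, SE 0.14), PRIM1 (-0.74, SE 0.13) and TK1 (-0.72, SE 0.18). Homologous recombination genes fell by less (3 fell, 0 rose and 39 of 42 did not pass, 7 and 0 over the list alone, mean -0.18, camera adjusted p = 2.61e-04, 0.0971 with an estimated correlation). Members included EXO1 (-0.79, SE 0.21), UBE2T (-0.65, SE 0.15) and RMI2 (-0.59, SE 0.13), while BRCA1 (-0.63, SE 0.20) and BRCA2 did not pass.

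ER stress and ATF4 genes fell in LNCaP with olaparib (6 fell, 0 rose and 16 of 22 did not pass, 7 and 0 over the list alone, mean -0.37, camera adjusted p = 9.19e-12). Members included SLC7A11 (-1.37, SE 0.16), SLC7A5 (-1.18, SE 0.14), PSAT1 (-0.88, SE 0.15) and ASNS (-0.72, SE 0.14). Androgen-induced genes rose slightly (5 rose, 0 fell and 35 of 40 did not pass, 12 and 0 over the list alone, mean 0.29, camera adjusted p = 4.58e-10). Members included ADAM7 (0.93, SE 0.14), RHOU (0.69, SE 0.16) and PMEPA1 (0.68, SE 0.14). Glucocorticoid-induced genes also rose (3 rose, 0 fell and 6 of 9 did not pass, 5 and 0 over the list alone, mean 0.39, camera adjusted p = 0.00142, 0.0529 with an estimated correlation). Members included SGK1 (1.58, SE 0.33), ERRFI1 (0.66, SE 0.15) and FKBP5 (0.47, SE 0.13).

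**Figure D2:**
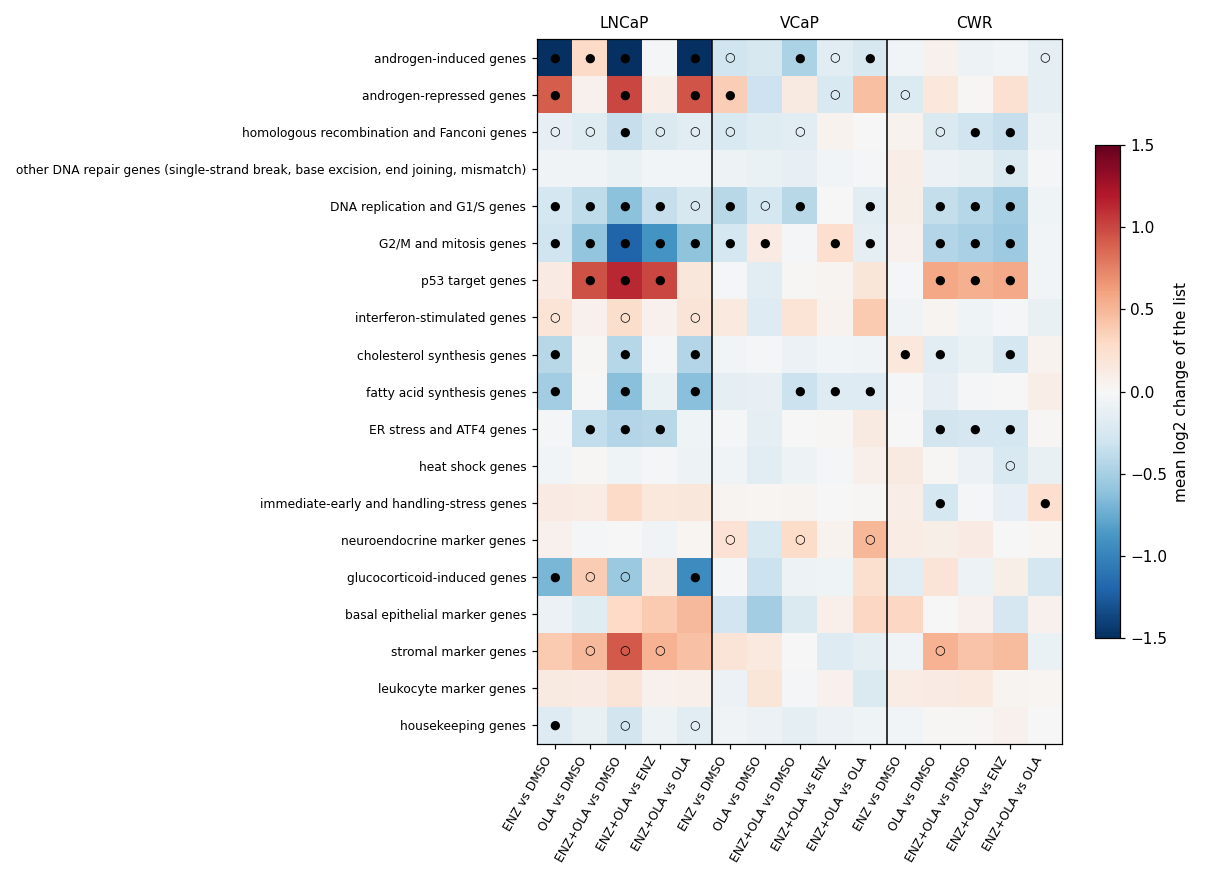
Mean log2 change of each gene list in each comparison. Filled circles mark lists past an adjusted p of 0.05 with camera under the preset and the estimated correlation, open circles those past it with the preset correlation alone. Values in the VCaP OLA columns hold the dim array.

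The combination changed more genes in LNCaP than either agent, holding the androgen-induced fall of enzalutamide and the p53 rise of olaparib, and lowering nearly all mitosis genes measured. Against DMSO, 2241 genes (1103 higher, 1138 lower) passed. With 35 arrays, 3264 genes (1671 higher, 1593 lower) did. With 36 arrays, 838 rose and 822 fell by at least 1.5-fold. IL1RN (3.65, SE 0.21), CEL (3.51, SE 0.30), TP53I3 (3.49, SE 0.24), OPRK1 (3.46, SE 0.18) and KCNU1 (3.40, SE 0.21) rose most. HPGD (at least 14.4-fold lower), TM4SF1 (-4.04, SE 0.21), KLK3 (-3.96, SE 0.35), AKAP12 (-3.86, SE 0.31) and TRPM8 (-3.72, SE 0.18) fell most.

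With the combination in LNCaP, androgen-induced genes fell (35 fell, 0 rose and 5 of 40 did not pass, 36 and 0 over the list alone, mean -1.75, camera adjusted p = 9.62e-55). Members included KLK2 (-3.52, SE 0.24) and TMPRSS2 (-3.01, SE 0.13). Androgen-repressed genes rose (6 rose, 0 fell and 4 of 10 did not pass, mean 1.00, camera adjusted p = 1.72e-06). The p53 targets rose (22 rose, 0 fell and 9 of 31 did not pass, 25 and 0 over the list alone, mean 1.13, camera adjusted p = 8.56e-24). Members included CDKN1A (2.44, SE 0.15), SESN1 (2.38, SE 0.16) and SPATA18 (2.32, SE 0.15). G2/M and mitosis genes fell (35 fell, 0 rose and 2 of 37 did not pass, 36 and 0 over the list alone, mean -1.20, camera adjusted p = 1.74e-50). Members included PLK1 (-1.82, SE 0.28), KIF20A (-1.82, SE 0.13), CCNA2 (-1.64, SE 0.15) and BUB1 (-1.53, SE 0.18), and MKI67 was at least 2.07-fold lower. DNA replication and G1/S genes fell (25 fell, 0 rose and 17 of 42 did not pass, 29 and 0 over the list alone, mean -0.62, camera adjusted p = 6.14e-17). Members included PRIM1 (-1.27, SE 0.13), POLE2 (-1.16, SE 0.14), DTL (-1.12, SE 0.23) and MCM5 (-1.08, SE 0.21). Homologous recombination and Fanconi genes fell (13 fell, 1 rose and 28 of 42 did not pass, 16 and 1 over the list alone, mean -0.34, camera adjusted p = 1.27e-05). Members included EXO1 (-1.14, SE 0.21), FANCB (-1.04, SE 0.30), RAD51AP1 (-0.99, SE 0.16), BRCA1 (-0.83, SE 0.20) and RAD54L (-0.72, SE 0.14). Other BRCA1 probes gave -0.94, 0.28 and 0.19. BARD1 (0.69, SE 0.22) rose and BRCA2 (-0.52, SE 0.29) and PARP1 (-0.22, SE 0.11) did not pass.

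The remaining lists past the threshold in LNCaP with the combination were those of cholesterol synthesis (12 fell, 1 rose and 9 of 22 did not pass, 15 and 3 over the list alone, mean -0.43, camera adjusted p = 6.33e-07), fatty acid synthesis (8 fell, 0 rose and 6 of 14 did not pass, 9 and 1 over the list alone, mean -0.62, camera adjusted p = 4.96e-06), ER stress and ATF4 (10 fell, 0 rose and 12 of 22 did not pass, 12 and 1 over the list alone, mean -0.44, camera adjusted p = 7.42e-07), glucocorticoid-induced (5 fell, 1 rose and 3 of 9 did not pass, mean -0.56, camera adjusted p = 0.00131, 0.0523 with an estimated correlation) and interferon-stimulated genes (6 rose, 0 fell and 17 of 23 did not pass, mean 0.26, camera adjusted p = 0.0194, 0.317 with an estimated correlation). Housekeeping genes fell with enzalutamide (2 fell, 0 rose and 10 of 12 did not pass, 3 and 0 over the list alone, mean -0.19, camera adjusted p = 0.00687), with the combination against DMSO (4 fell, 0 rose and 8 of 12 did not pass, mean -0.27, camera adjusted p = 0.00938, 0.0540 with an estimated correlation) and against olaparib (2 fell, 0 rose and 10 of 12 did not pass, 3 and 0 over the list alone, mean -0.17, camera adjusted p = 0.0353, 0.115 with an estimated correlation, 0.0756 with 35 arrays). The falls were led by PGK1 (-1.01, SE 0.13), HPRT1 (-0.63, SE 0.14) and B2M (-0.47, SE 0.10) in the combination, and the mean was negative under each of the 4 scalings in these 3 comparisons.

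Adding olaparib to enzalutamide in LNCaP raised p53 targets and lowered mitosis genes, and adding enzalutamide to olaparib lowered androgen-induced genes and lowered mitosis genes further. Between the combination and enzalutamide, 412 genes (181 higher, 231 lower) differed. With 35 arrays, 718 genes (325 higher, 393 lower) did. CEL (3.18, SE 0.30), TP53I3 (2.89, SE 0.24), APOBEC3H (2.37, SE 0.14), CDKN1A (2.24, SE 0.15) and FAXDC2 (at least 3.46-fold higher) rose most. PLOD2 (-3.01, SE 0.19), COXFA4L2 (-2.31, SE 0.29), TMEM45A (-2.07, SE 0.21), SLC16A3 (-1.74, SE 0.29) and KISS1R (-1.61, SE 0.22) fell most. The p53 list rose (17 rose, 0 fell and 14 of 31 did not pass, 23 and 0 over the list alone, mean 1.01, camera adjusted p = 2.67e-45). Mitosis genes fell (32 fell, 0 rose and 5 of 37 did not pass, 35 and 0 over the list alone, mean -0.89, camera adjusted p = 3.55e-74). Replication genes fell (9 fell, 0 rose and 33 of 42 did not pass, 17 and 1 over the list alone, mean -0.35, camera adjusted p = 2.15e-14). Homologous recombination genes fell (3 fell, 0 rose and 39 of 42 did not pass, 6 and 1 over the list alone, mean -0.21, camera adjusted p = 8.73e-05, 0.0751 with an estimated correlation) and ER stress and ATF4 genes fell (8 fell, 0 rose and 14 of 22 did not pass, 12 and 0 over the list alone, mean -0.41, camera adjusted p = 1.46e-12).

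Between the combination and olaparib in LNCaP, 1124 genes (525 higher, 599 lower) differed. With 35 arrays, 1691 genes (841 higher, 850 lower) did. DDC (3.47, SE 0.13), LRRC31 (at least 10.4-fold higher), LRRN1 (3.40, SE 0.23), OPRK1 (3.24, SE 0.18) and CAMK2N1 (2.95, SE 0.21) rose most. HPGD (at least 18.0-fold lower), KLK3 (-4.06, SE 0.35), TRPM8 (-4.05, SE 0.18), ADH1A (at least 12.6-fold lower) and TARP (-3.80, SE 0.26) fell most. Androgen-induced genes fell (36 fell, 0 rose and 4 of 40 did not pass, mean -2.04, camera adjusted p = 5.76e-96). Androgen-repressed genes rose (6 rose, 0 fell and 4 of 10 did not pass, mean 0.94, camera adjusted p = 6.61e-08). Mitosis genes fell (27 fell, 0 rose and 10 of 37 did not pass, 33 and 0 over the list alone, mean -0.60, camera adjusted p = 4.56e-29). Members included KIF20A (-1.02, SE 0.13) and CCNB1 (-0.87, SE 0.096). Lower lists were also those of cholesterol synthesis (12 fell, 1 rose and 9 of 22 did not pass, mean -0.44, camera adjusted p = 9.65e-11), fatty acid synthesis (5 fell, 0 rose and 9 of 14 did not pass, mean -0.62, camera adjusted p = 7.17e-07), glucocorticoid-induced (5 fell, 0 rose and 4 of 9 did not pass, mean -0.94, camera adjusted p = 1.19e-07), replication (4 fell, 0 rose and 38 of 42 did not pass, mean -0.24, camera adjusted p = 2.13e-05, 0.0770 with an estimated correlation) and homologous recombination genes (3 fell, 1 rose and 38 of 42 did not pass, mean -0.17, camera adjusted p = 0.0105, 0.260 with an estimated correlation). Interferon-stimulated genes were higher (2 rose, 0 fell and 21 of 23 did not pass, mean 0.19, camera adjusted p = 0.0431, 0.389 with an estimated correlation).

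Most single genes in LNCaP did not depart from the sum of the 2 single effects on the log2 scale. 3 genes did (2 above the sum, 1 below), and 14 with 35 arrays. They were LOX (1.59, SE 0.24) and TUBB2B (0.91, SE 0.15), which fell with each agent and by less than the sum with both, and COL4A6 (-1.27, SE 0.23), which rose with olaparib and not with the combination. Next were CCNB1 (-0.71, SE 0.14) and UGT2B4 (1.37, SE 0.27), each at adjusted p = 0.0575. As groups, mitosis genes lay below the sum (mean -0.30, camera adjusted p = 4.75e-18, 8.47e-05 with an estimated correlation). So did androgen-induced genes (mean -0.32, 6.60e-11 and 0.00888). These were 2 of 15 tests (5 lists, 3 lines), adjusted over the 15 and added after the gene results were seen. The other 13 did not pass, replication, homologous recombination and p53 lists in LNCaP and all 5 in VCaP and CWR (adjusted p from 0.113). KLK3 lay below the sum (-1.13, SE 0.49) without passing.

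**Figure D3:**
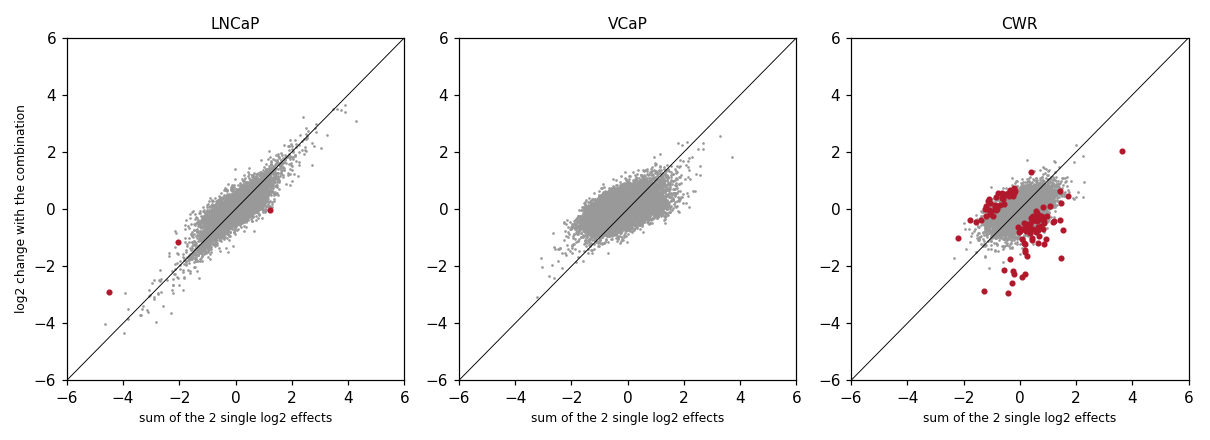
Log2 change with the combination against the sum of the 2 single log2 effects, 1 point per gene. Red points passed the test of a departure from the sum (limma adjusted p under 0.05, 36 arrays). The line marks equality. The OLA groups of VCaP include the dim array.

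In VCaP, enzalutamide lowered part of the androgen-induced list and lowered DNA replication genes. Against DMSO, 528 genes (327 higher, 201 lower) passed. With 35 arrays, 1054 genes (602 higher, 452 lower) did. CCN3 (3.47, SE 0.31), HABP2 (2.36, SE 0.22), VAV3 (2.31, SE 0.20), CLEC3A (2.23, SE 0.44) and HOPX (2.21, SE 0.39) rose most. NPY (-2.77, SE 0.12), TRPM8 (-2.16, SE 0.18), SLC45A3 (-2.01, SE 0.15), SLC2A3 (at least 2.95-fold lower) and CYP1B1 (-1.83, SE 0.19) fell most.

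Androgen-induced genes shifted down in VCaP with enzalutamide (6 fell, 1 rose and 33 of 40 did not pass, 13 and 1 over the list alone, mean -0.30, camera adjusted p = 4.53e-06, 0.0553 with an estimated correlation). Members included PMEPA1 (-1.38, SE 0.14) and PTGER4 (-0.64, SE 0.17), while HPGD (1.46, SE 0.16) rose. KLK3 (-1.20, SE 0.35) and FKBP5 (-0.44, SE 0.13) did not pass with 36 arrays and did with 35 (adjusted p = 2.46e-04 and 0.0256). Androgen-repressed genes rose (3 rose, 1 fell and 6 of 10 did not pass, 4 and 1 over the list alone, mean 0.37, camera adjusted p = 0.00417). Members included PEG10 (0.89, SE 0.15) and FOLH1 (0.71, SE 0.16), against UGT2B28 (-0.81, SE 0.17). DNA replication and G1/S genes fell (10 fell, 0 rose and 32 of 42 did not pass, 23 and 0 over the list alone, mean -0.42, camera adjusted p = 5.22e-18). Members included PRIM1 (-0.80, SE 0.13), GINS3 (-0.76, SE 0.19), MCM2 (-0.76, SE 0.19) and E2F2 (-0.67, SE 0.14). Mitosis genes fell by less (1 fell, 0 rose and 36 of 37 did not pass, 4 and 0 over the list alone, mean -0.27, camera adjusted p = 2.64e-09). Homologous recombination and Fanconi genes fell (4 fell, 0 rose and 38 of 42 did not pass, 5 and 0 over the list alone, mean -0.23, camera adjusted p = 3.63e-05, 0.0606 with an estimated correlation). Members included EXO1 (-0.75, SE 0.21), RAD51C (-0.64, SE 0.17), UBE2T (-0.56, SE 0.15) and RAD54L (-0.55, SE 0.14). Neuroendocrine marker genes rose (1 rose, 0 fell and 11 of 12 did not pass, 4 and 1 over the list alone, mean 0.22, camera adjusted p = 0.0154, 0.0923 with an estimated correlation). Members included CHGB (0.66, SE 0.15).

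Few genes passed in VCaP with olaparib, in a group that holds the dim array. Against DMSO, 13 genes (1 higher, 12 lower) passed, and 11 genes (8 higher, 3 lower) with the 2 other OLA arrays, of which 4 were called in both with the same direction. Array quality weights, which also weigh down the dim array and rest the OLA group mostly on replicate 2, gave 1471. Leaving out 1 array at a time gave 1 to 4176. 3900 genes had an unadjusted p under 0.05 with 36 arrays and 1126 with 35. FBLN1 (1.23, SE 0.20) rose and RNY4 (-1.99, SE 0.33), B4GALT2 (-1.35, SE 0.27), UGT2B28 (-1.32, SE 0.17), MYH13 (-1.28, SE 0.21) and AFF3 (-1.24, SE 0.22) fell, and of these FBLN1, UGT2B28 and MYH13 passed with 35 arrays too. The p53 list did not pass (0 fell, 0 rose and 31 of 31 did not pass, mean -0.16, camera adjusted p = 0.866), nor did CDKN1A (0.37, SE 0.15). Mitosis genes shifted up (0 rose, 0 fell and 37 of 37 did not pass, 2 and 0 over the list alone, mean 0.12, camera adjusted p = 3.02e-06), which had a mean of -1.01 and the opposite test direction under median scaling, where the median of all genes was -0.72. Replication genes shifted down (0 fell, 0 rose and 42 of 42 did not pass, 1 and 0 over the list alone, mean -0.26, camera adjusted p = 0.0445, 0.432 with an estimated correlation). With 35 arrays the means were -0.016 (p53), 0.18 (mitosis) and -0.094 (replication), with the same calls, and fatty acid synthesis genes passed lower (-0.14, camera adjusted p = 0.0319).

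With the combination in VCaP, androgen-induced and DNA replication genes fell as with enzalutamide, and the p53 list did not pass. Against DMSO, 1239 genes (645 higher, 594 lower) passed. With 35 arrays, 2491 genes (1263 higher, 1228 lower) did. With 36 arrays, 514 rose and 372 fell by at least 1.5-fold. CCN3 (2.57, SE 0.31), HABP2 (2.34, SE 0.22), SCUBE2 (2.33, SE 0.35), IGFBP5 (2.30, SE 0.24) and HOPX (2.26, SE 0.39) rose most. NPY (-3.08, SE 0.12), TRPM8 (-2.42, SE 0.18), CYP1B1 (-2.35, SE 0.19), DNASE2B (-2.07, SE 0.20) and SLC2A3 (at least 2.89-fold lower) fell most. Androgen-induced genes fell (15 fell, 1 rose and 24 of 40 did not pass, 17 and 2 over the list alone, mean -0.48, camera adjusted p = 2.30e-10). Members included SLC45A3 (-1.97, SE 0.15), PMEPA1 (-1.86, SE 0.14), KLK3 (-1.54, SE 0.35) and FKBP5 (-0.69, SE 0.13), against HPGD (0.86, SE 0.16). DNA replication and G1/S genes fell (15 fell, 0 rose and 27 of 42 did not pass, 23 and 0 over the list alone, mean -0.42, camera adjusted p = 7.19e-13). Members included CCNE2 (-1.18, SE 0.18), MCM6 (-0.94, SE 0.15) and MCM4 (-0.84, SE 0.13). Homologous recombination genes fell (4 fell, 0 rose and 38 of 42 did not pass, 6 and 0 over the list alone, mean -0.17, camera adjusted p = 0.0104, 0.260 with an estimated correlation). Members included EXO1 (-0.92, SE 0.21), RAD51AP1 (-0.69, SE 0.16), NBN (-0.60, SE 0.19) and RAD54L (-0.44, SE 0.14). Fatty acid synthesis genes fell (2 fell, 0 rose and 12 of 14 did not pass, 8 and 0 over the list alone, mean -0.33, camera adjusted p = 4.42e-04). Members included ME1 (-0.76, SE 0.18) and ELOVL5 (-0.63, SE 0.16). Neuroendocrine marker genes rose (2 rose, 0 fell and 10 of 12 did not pass, 3 and 1 over the list alone, mean 0.28, camera adjusted p = 0.0350, 0.142 with an estimated correlation). Members included NTS (1.13, SE 0.21) and ENO2 (1.00, SE 0.29). The p53 (0 rose, 2 fell and 29 of 31 did not pass, mean 0.012, camera adjusted p = 0.916), mitosis (1 fell, 0 rose and 36 of 37 did not pass, mean -0.02, camera adjusted p = 0.854) and androgen-repressed lists (3 rose, 1 fell and 6 of 10 did not pass, mean 0.13, camera adjusted p = 0.547) did not pass. The 2 p53 targets that fell were FAS (-1.06, SE 0.24) and AEN (-0.65, SE 0.17). The 2 other kept KLK3 probes did not change here (0.047 and -0.18), while all 3 fell in LNCaP.

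Between the combination and enzalutamide in VCaP, 11 genes (5 higher, 6 lower) passed. With 35 arrays, 196 (103 higher, 93 lower) did. Leaving out each array in turn gave 0 to 432. SNORD3A (0.97, SE 0.18), ASF1B (0.86, SE 0.15), RNU1-3 (0.82, SE 0.17), HMMR (0.66, SE 0.13) and UBE2C (0.65, SE 0.11) were higher and PCMTD2 (-0.95, SE 0.16), ATP8A1 (-0.83, SE 0.17), ZNF280C (-0.71, SE 0.14), CWH43 (-0.67, SE 0.13) and PAIP1 (-0.66, SE 0.12) lower. Mitosis genes were higher with the combination (2 rose, 0 fell and 35 of 37 did not pass, 9 and 0 over the list alone, mean 0.25, camera adjusted p = 1.21e-09). The ENZ+OLA arrays differed (SD of pairs 0.41 to 0.57, 0.27 to 0.38 in DMSO and ENZ). PLK1 was 7.85, 7.84 and, in replicate 3, 6.67 (ENZ from 6.98). Androgen-induced genes were lower (0 fell, 0 rose and 40 of 40 did not pass, 3 and 0 over the list alone, mean -0.17, camera adjusted p = 9.83e-05, 0.106 with an estimated correlation), and so were fatty acid synthesis (0 fell, 0 rose and 14 of 14 did not pass, mean -0.19, camera adjusted p = 0.00417) and androgen-repressed genes (0 fell, 0 rose and 10 of 10 did not pass, mean -0.23, camera adjusted p = 0.0356, 0.122 with an estimated correlation, 0.0665 with 35 arrays). Between the combination and olaparib, 1996 genes (1484 higher, 512 lower) passed, but 598 (312 higher, 286 lower) with 35 arrays. Of these, 422 were in both with the same direction. Called in both were CCN3 (2.78, SE 0.31), HABP2 (2.59, SE 0.22) and HOPX (2.55, SE 0.39), which rose, and NPY (-2.62, SE 0.12), TRPM8 (-1.97, SE 0.18) and MCCC2 (-1.92, SE 0.26), which fell.

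In that comparison with olaparib in VCaP, lists past the threshold were androgen-induced (10 fell, 2 rose and 28 of 40 did not pass, mean -0.23, camera adjusted p = 1.36e-06), replication (8 fell, 0 rose and 34 of 42 did not pass, mean -0.16, camera adjusted p = 9.98e-07), mitosis (3 fell, 0 rose and 34 of 37 did not pass, mean -0.14, camera adjusted p = 2.13e-05), fatty acid synthesis (3 fell, 1 rose and 10 of 14 did not pass, mean -0.20, camera adjusted p = 0.00698, 0.0504 with 35 arrays) and neuroendocrine marker genes (4 rose, 0 fell and 8 of 12 did not pass, mean 0.50, camera adjusted p = 0.00904, 0.0697 with an estimated correlation). Under median scaling the test direction of the mitosis and fatty acid lists turned. With 35 arrays the means were -0.39, -0.33, -0.20, -0.18 and 0.31, and homologous recombination genes passed lower (-0.16, camera adjusted p = 0.00763). No gene passed the test of a departure from the sum in VCaP with limma and 36 arrays, where 1887 genes had an unadjusted p under 0.05, and 2 passed with 35 arrays. The smallest p-values were those of UGT2B28 (1.33, SE 0.24), BEX2 (0.86, SE 0.18) and MYH13 (1.39, SE 0.30), adjusted p from 0.135 to 0.182.

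**Figure D4:**
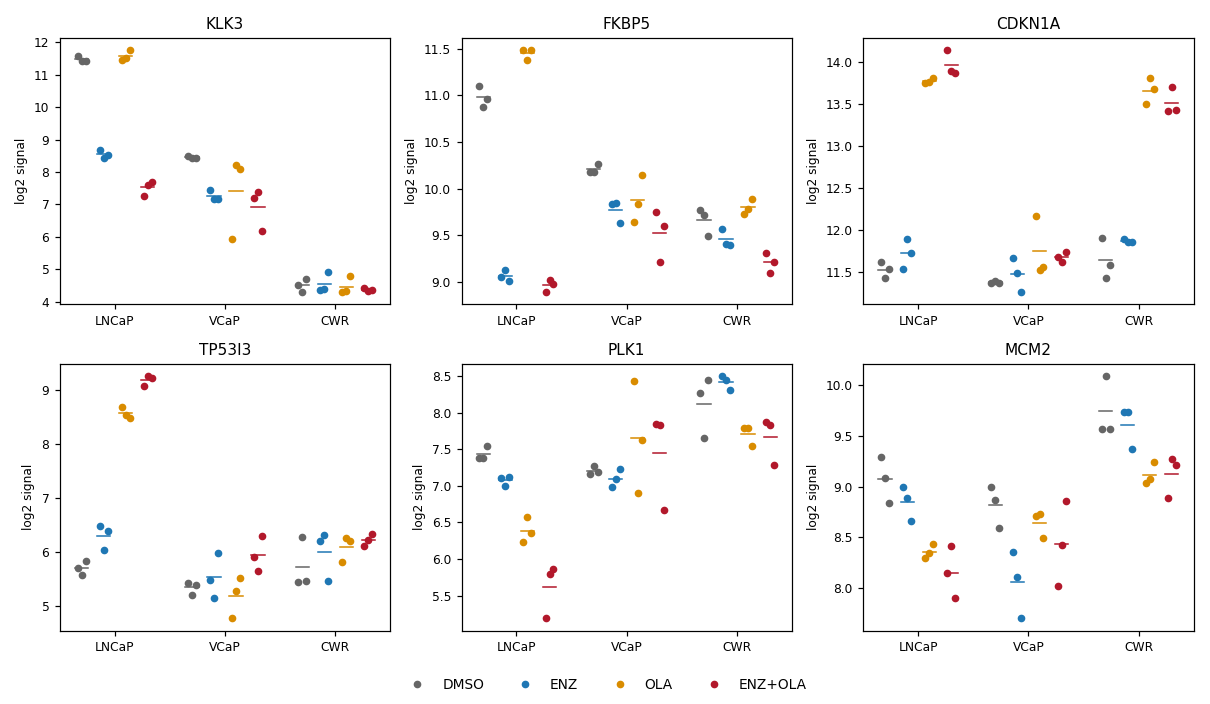
Log2 signal of 6 genes on each array, with group means. KLK3 and FKBP5 are androgen-induced, CDKN1A and TP53I3 p53 targets, PLK1 a mitosis and MCM2 a replication gene. PLK1 and TP53I3 were chosen after their values were seen. The VCaP OLA group holds the dim array.

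In CWR, few genes passed with enzalutamide, and the androgen-induced list did not. Against DMSO, 16 genes (5 higher, 11 lower) passed, and 37 genes (14 higher, 23 lower) with 35 arrays, with 1613 genes at an unadjusted p under 0.05. The count rests on single arrays: it was 5 to 173 with 1 array left out, highest without DMSO replicate 1, and 61 with array quality weights. BAMBI (1.27, SE 0.17), KCND2 (0.80, SE 0.14), ZGPAT (0.74, SE 0.15), DDIT4L (0.66, SE 0.13) and COPRS (0.56, SE 0.10) rose most. PDK4 (-1.11, SE 0.18), H2BW2 (at least 1.74-fold lower), IRS1 (-0.99, SE 0.16), MAOA (at least 1.58-fold lower) and EDA2R (at least 1.49-fold lower) fell most. No panel gene passed, with KLK3 near background. Androgen-induced genes did not pass (0 fell, 0 rose and 40 of 40 did not pass, mean -0.04, camera adjusted p = 0.356), but 6 of the 40, below background in both groups, could not show a fall. The mean of the other 34 was -0.042 (SD 0.27). Androgen-repressed genes shifted down slightly (0 fell, 0 rose and 10 of 10 did not pass, 2 and 0 over the list alone, mean -0.21, camera adjusted p = 0.0171, 0.0824 with an estimated correlation) and cholesterol synthesis genes up (0 rose, 0 fell and 22 of 22 did not pass, 1 and 0 over the list alone, mean 0.16, camera adjusted p = 0.00213).

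Olaparib raised p53 target genes in CWR and lowered mitosis and replication genes. Against DMSO, 247 genes (123 higher, 124 lower) passed. With 35 arrays, 601 genes (301 higher, 300 lower) did. With 36 arrays, 96 rose and 109 fell by at least 1.5-fold. CYP1A2 (3.02, SE 0.17), ELAVL2 (2.04, SE 0.36), CDKN1A (2.02, SE 0.15), ACTA2 (1.96, SE 0.17) and GDF15 (1.91, SE 0.31) rose most. ITM2A (-1.76, SE 0.23), DHRS2 (-1.60, SE 0.18), NIBAN1 (-1.29, SE 0.25), CBX1 (-1.25, SE 0.27) and ACP3 (at least 1.85-fold lower) fell most. The p53 list rose (10 rose, 0 fell and 21 of 31 did not pass, 17 and 0 over the list alone, mean 0.58, camera adjusted p = 4.83e-21). Members included TP53INP1 (1.18, SE 0.19) and SPATA18 (1.10, SE 0.15). Mitosis genes fell (11 fell, 0 rose and 26 of 37 did not pass, 23 and 0 over the list alone, mean -0.44, camera adjusted p = 2.50e-23). Members included AURKB (-1.04, SE 0.19), FOXM1 (-0.75, SE 0.19), NDC80 (-0.74, SE 0.15) and TOP2A (-0.69, SE 0.14). Replication genes fell (8 fell, 0 rose and 34 of 42 did not pass, 15 and 0 over the list alone, mean -0.36, camera adjusted p = 6.20e-15). Members included GINS4 (-1.01, SE 0.22), MCM5 (-0.97, SE 0.21), TYMS (-0.85, SE 0.13) and PRIM1 (-0.76, SE 0.13). Homologous recombination genes shifted down (1 fell, 0 rose and 41 of 42 did not pass, mean -0.22, camera adjusted p = 1.78e-05, 0.0526 with an estimated correlation). Members included RMI2 (-0.57, SE 0.13).

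ER stress and ATF4 genes fell in CWR with olaparib (4 fell, 0 rose and 18 of 22 did not pass, 6 and 0 over the list alone, mean -0.28, camera adjusted p = 4.11e-06). Members included DDIT3 (-0.88, SE 0.21), PSAT1 (-0.83, SE 0.15), PHGDH (-0.82, SE 0.13) and ASNS (-0.79, SE 0.14). Immediate-early and handling-stress genes fell (2 fell, 0 rose and 9 of 11 did not pass, 3 and 1 over the list alone, mean -0.27, camera adjusted p = 0.0248). Members included ATF3 (-0.96, SE 0.21) and FOS (-0.65, SE 0.14). This list call was lost with probes detected on all arrays (mean -0.012). Cholesterol synthesis genes shifted down with no single member past the threshold (0 fell, 0 rose and 22 of 22 did not pass, mean -0.16, camera adjusted p = 0.00687).

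With the combination in CWR came the p53 rise and the falls of cell division genes seen with olaparib, and a set of falls that did not pass with either agent alone. Against DMSO, 935 genes (436 higher, 499 lower) passed. With 35 arrays, 1715 genes (836 higher, 879 lower) did. With 36 arrays, 291 rose and 351 fell by at least 1.5-fold. The largest rises were GDF15 (2.26, SE 0.31), CYP1A2 (2.04, SE 0.17), CDKN1A (1.87, SE 0.15), MIR1974 (1.72, SE 0.43) and BTG2 (1.67, SE 0.25). A second CDKN1A probe, which is dimmer, did not change (0.13). The largest falls were HES7 (-2.87, SE 0.20), ZNF121 (-2.61, SE 0.47), GNL3L (-2.26, SE 0.27), RNA28SN5 (-2.26, SE 0.15) and TNFAIP8L1 (-2.12, SE 0.26), none of which passed with enzalutamide or olaparib. Of these 5, the departure from the sum of the single effects passed for HES7, GNL3L, RNA28SN5 and TNFAIP8L1 and not for ZNF121 (adjusted p = 0.0997). The p53 list rose (9 rose, 0 fell and 22 of 31 did not pass, 13 and 1 over the list alone, mean 0.54, camera adjusted p = 2.65e-12). Mitosis genes fell (14 fell, 0 rose and 23 of 37 did not pass, 26 and 0 over the list alone, mean -0.48, camera adjusted p = 9.71e-21). Members included AURKB (-0.92, SE 0.19), CDC25C (-0.78, SE 0.13) and KIF11 (-0.75, SE 0.16). Replication genes fell (11 fell, 0 rose and 31 of 42 did not pass, 18 and 0 over the list alone, mean -0.43, camera adjusted p = 1.77e-13). Members included GINS4 (-2.06, SE 0.22), TK1 (-0.76, SE 0.18) and MCM4 (-0.76, SE 0.13). Homologous recombination and Fanconi genes fell (7 fell, 0 rose and 35 of 42 did not pass, 9 and 0 over the list alone, mean -0.30, camera adjusted p = 2.66e-06). Members included BARD1 (-1.08, SE 0.22), RBBP8 (-0.88, SE 0.18), FANCI (-0.73, SE 0.15) and EXO1 (-0.72, SE 0.21). ER stress and ATF4 genes fell (4 fell, 0 rose and 18 of 22 did not pass, 5 and 1 over the list alone, mean -0.26, camera adjusted p = 2.47e-04). FKBP5 (-0.45, SE 0.13) fell, and the androgen-induced list did not pass (5 fell, 0 rose and 35 of 40 did not pass, mean -0.077, median 0.00038, camera adjusted p = 0.385).

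Adding olaparib to enzalutamide in CWR changed more genes than adding enzalutamide to olaparib. Between the combination and enzalutamide, 1539 genes (702 higher, 837 lower) differed. With 35 arrays, 2623 genes (1217 higher, 1406 lower) did. GDF15 (2.19, SE 0.31), MIR1974 (2.08, SE 0.43), PHLDA3 (1.74, SE 0.13), ACTA2 (1.71, SE 0.17) and CDKN1A (1.64, SE 0.15) rose most. ZNF121 (-2.67, SE 0.47), GNL3L (-2.52, SE 0.27), NFAT5 (-2.25, SE 0.29), TNFAIP8L1 (-2.12, SE 0.26) and RNA28SN5 (-2.05, SE 0.15) fell most. The p53 list rose (13 rose, 0 fell and 18 of 31 did not pass, mean 0.57, camera adjusted p = 2.14e-11), mitosis (23 fell, 0 rose and 14 of 37 did not pass, 28 and 0 over the list alone, mean -0.55, camera adjusted p = 1.57e-21) and replication genes fell (21 fell, 0 rose and 21 of 42 did not pass, 28 and 1 over the list alone, mean -0.52, camera adjusted p = 4.91e-16). So did homologous recombination and Fanconi genes (10 fell, 0 rose and 32 of 42 did not pass, 11 and 0 over the list alone, mean -0.35, camera adjusted p = 4.75e-06). Members included EXO1 (-1.16, SE 0.21), BARD1 (-1.09, SE 0.22), FANCI (-0.97, SE 0.15) and BRCA1 (-0.87, SE 0.20, other probes -1.05, 0.16 and 0.11). Other DNA repair genes passed here alone of the 15 comparisons (7 fell, 0 rose and 20 of 27 did not pass, 8 and 0 over the list alone, mean -0.21, camera adjusted p = 0.00698). Members included POLQ (-0.99, SE 0.19), MSH6 (-0.73, SE 0.16), OGG1 (-0.56, SE 0.17) and PARP1 (-0.36, SE 0.11). Cholesterol synthesis (7 fell, 1 rose and 14 of 22 did not pass, 10 and 1 over the list alone, mean -0.26, camera adjusted p = 4.42e-04), ER stress and ATF4 (7 fell, 1 rose and 14 of 22 did not pass, 11 and 1 over the list alone, mean -0.26, camera adjusted p = 5.30e-04) and heat shock genes (2 fell, 0 rose and 8 of 10 did not pass, 4 and 0 over the list alone, mean -0.23, camera adjusted p = 0.0273, 0.260 with an estimated correlation) were lower.

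Between the combination and olaparib in CWR, 216 genes (53 higher, 163 lower) differed. With 35 arrays, 509 genes (177 higher, 332 lower) did. SAMD11 (1.14, SE 0.23), PKD1 (1.01, SE 0.25), BAMBI (0.96, SE 0.17), RNF166 (0.95, SE 0.24) and SOX9 (0.93, SE 0.23) rose most. NFAT5 (-2.64, SE 0.29), HES7 (-2.44, SE 0.20), ZNF121 (-2.31, SE 0.47), RNA28SN5 (-2.25, SE 0.15) and SNORD13 (-2.19, SE 0.32) fell most. Androgen-induced genes were slightly lower (4 fell, 0 rose and 36 of 40 did not pass, 5 and 0 over the list alone, mean -0.14, camera adjusted p = 0.0133, 0.317 with an estimated correlation). Members included PTGER4 (-0.72, SE 0.17), ABCC4 (-0.70, SE 0.17), HPGD (-0.64, SE 0.16) and FKBP5 (-0.59, SE 0.13). Immediate-early and handling-stress genes were higher (1 rose, 0 fell and 10 of 11 did not pass, mean 0.25, camera adjusted p = 0.0113). Members included FOS (0.55, SE 0.14).

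In CWR, 110 genes departed from the sum of the single effects (38 above, 72 below), and 404 with 35 arrays. With 1 array left out the count was 34 to 439, lowest without DMSO replicate 2. That array stood apart from its replicates (SD of the log2 difference 0.49 and 0.47, against 0.31 to 0.34 for other CWR pairs). The 5 with the smallest p-values were all below it. They were RNA28SN5 (-2.05, SE 0.22), a 28S ribosomal RNA, and 4 loci without an approved name, LOC100134364 (-2.51, SE 0.24), LOC441763 (-2.47, SE 0.26), LOC100133565 (-1.92, SE 0.21) and LOC100132394 (-2.33, SE 0.26). Of the 110 genes, 80 had a protein-coding entry in the reference. No panel gene passed.

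The responses differed between the lines, among them those of androgen-induced genes with enzalutamide and of p53 targets with olaparib. By a moderated F test of the differences, 590 genes responded differently to enzalutamide (1174 with 35 arrays), 186 to olaparib (222) and 1470 to the combination (2690). With enzalutamide the smallest p-values were those of HPGD (at least 14.0-fold lower in LNCaP, 1.46 in VCaP, -0.53 in CWR, adjusted p = 2.63e-16), TMPRSS2 (-3.31 in LNCaP, 0.26 in VCaP, 0.15 in CWR, adjusted p = 4.24e-14) and NPY (-2.77 in VCaP, below background in LNCaP and CWR, adjusted p = 2.72e-13), with TRIM51 and the pseudogene ZNF812P. KLK3 (-2.93 in LNCaP, -1.20 in VCaP, below background in CWR, adjusted p = 7.47e-04) also differed.

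With olaparib the smallest p-values were those of CYP1A2 (3.02 in CWR, below background in LNCaP and VCaP, adjusted p = 1.28e-09), POTEC (1.85 in LNCaP, -0.20 in CWR, below background in VCaP, adjusted p = 1.16e-08), SPATA18 (2.42 in LNCaP, 1.10 in CWR, below background in VCaP, adjusted p = 3.04e-07), SERPINB5 and CEACAM1. CDKN1A (2.25 in LNCaP, 0.37 in VCaP, 2.02 in CWR, adjusted p = 2.03e-06) differed as well. With the combination, HPGD (at least 14.4-fold lower in LNCaP, 0.86 in VCaP, -0.87 in CWR, adjusted p = 3.73e-15), NPY (-3.08 in VCaP, below background in LNCaP and CWR, adjusted p = 8.52e-14), AGR2 (-2.96 in LNCaP, 0.062 in VCaP, -0.44 in CWR, adjusted p = 7.82e-13), TMPRSS2 and the pseudogene GRM5P1 came first, and MKI67 (at least 2.07-fold lower in LNCaP, 0.25 in VCaP, -0.56 in CWR, adjusted p = 0.0184) passed. BRCA1, BRCA2, PARP1 and MCM2 did not differ between the lines at the threshold with any of the 3 treatments.

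As lists, a comparison added after the gene results were seen and adjusted over its 45 tests, the androgen-induced list fell less with enzalutamide in VCaP (VCaP less LNCaP 1.42, camera adjusted p = 9.49e-69) than in LNCaP and did not pass in CWR (CWR less LNCaP 1.68, camera adjusted p = 9.49e-69). The mean p53 change with olaparib was lower in VCaP (VCaP less LNCaP -1.12, camera adjusted p = 4.78e-25), where the list did not pass, and in CWR (CWR less LNCaP -0.38, camera adjusted p = 5.16e-07). With 35 arrays VCaP less LNCaP was -0.97. Of the 31 p53 members, 27 had signal in both VCaP and LNCaP, over which the difference was -1.13 (camera adjusted p = 1.02e-22). With the combination, mitosis genes fell in LNCaP, fell by less in CWR (CWR less LNCaP 0.72, camera adjusted p = 6.92e-23) and did not pass in VCaP (VCaP less LNCaP 1.18, camera adjusted p = 8.38e-50). The differences in homologous recombination genes with the combination were small (VCaP less LNCaP 0.17, camera adjusted p = 0.0340, 0.269 with an estimated correlation, and CWR less LNCaP 0.044, camera adjusted p = 0.421).

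Markers of other cell types gave no list call that held under both camera correlations. Basal epithelial (2 of 9 genes measured) and leukocyte lists (5 of 10) did not pass in any of the 15 comparisons. The stromal list (4 of 12) passed in 4 comparisons, each through ACTA2 alone: OLA vs DMSO (ACTA2 1.93, camera adjusted p = 0.0254, 0.142 with an estimated correlation, 0.0514 with 35 arrays), ENZ+OLA vs DMSO (ACTA2 2.55, camera adjusted p = 0.00851, 0.0824 with an estimated correlation) and ENZ+OLA vs ENZ (ACTA2 1.95, camera adjusted p = 0.0101, 0.0906 with an estimated correlation) in LNCaP and OLA vs DMSO (ACTA2 1.96, camera adjusted p = 0.0143, 0.108 with an estimated correlation) in CWR.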

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

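The list tests of line differences, with and without members lacking signal, the 3 tests on the dim array, the test of androgen-driven transcription and the covariate test with 35 arrays were chosen after the results were seen, the other tests before theirs. Responses that differed between the cell lines (limma F test, adjusted p under 0.05) are given as the range of the log2 changes over the lines with signal above background, n = 3 per group. With enzalutamide these were HPGD at least 5.27, TMPRSS2 3.57, ZNF812P 3.57, TRIM51 4.36, KLK3 1.74, FKBP5 1.72, RAD54L 0.78. With olaparib they were POTEC 2.05, SPATA18 1.31, FKBP5 0.80, CDKN1A 1.87, of which the FKBP5 difference did not pass with 35 arrays. With the combination they were HPGD at least 4.71, AGR2 3.02, TMPRSS2 3.01, GRM5P1 5.31, KLK3 2.42, FKBP5 1.57, CDKN1A 2.14, MKI67 at least 1.3. NPY (enzalutamide and the combination, VCaP), CYP1A2 (olaparib, CWR), SERPINB5 and CEACAM1 (olaparib, LNCaP) also differed but were above background in only the line named, so no range is given.

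The lists below differed between lines by camera (adjusted p under 0.05), given as differences of mean log2 change, with the adjusted p under an estimated correlation in brackets where it did not pass. Androgen-induced genes: with ENZ VCaP less LNCaP 1.42, CWR less LNCaP 1.68, VCaP less CWR -0.26 (0.121), with OLA VCaP less LNCaP -0.53, CWR less LNCaP -0.22 (0.0554), VCaP less CWR -0.31 (0.275), with ENZ+OLA VCaP less LNCaP 1.27, CWR less LNCaP 1.67, VCaP less CWR -0.40. Homologous recombination and Fanconi genes: with ENZ CWR less LNCaP 0.18 (0.199), VCaP less CWR -0.28 (0.0614), with OLA VCaP less CWR 0.045 (0.207), with ENZ+OLA VCaP less LNCaP 0.17 (0.269). DNA replication and G1/S genes: with ENZ VCaP less LNCaP -0.15 (0.199), CWR less LNCaP 0.36, VCaP less CWR -0.51, with OLA VCaP less LNCaP 0.12 (0.0627), VCaP less CWR 0.096 (0.0840), with ENZ+OLA VCaP less LNCaP 0.20 (0.199), CWR less LNCaP 0.19 (0.174). G2/M and mitosis genes: with ENZ CWR less LNCaP 0.37, VCaP less CWR -0.33, with OLA VCaP less LNCaP 0.71, CWR less LNCaP 0.15 (0.0840), VCaP less CWR 0.56, with ENZ+OLA VCaP less LNCaP 1.18, CWR less LNCaP 0.72, VCaP less CWR 0.46. P53 target genes: with ENZ VCaP less LNCaP -0.14 (0.135), CWR less LNCaP -0.15 (0.144), with OLA VCaP less LNCaP -1.12, CWR less LNCaP -0.38, VCaP less CWR -0.74, with ENZ+OLA VCaP less LNCaP -1.11, CWR less LNCaP -0.59, VCaP less CWR -0.52. Over members with signal in both lines, the p53 difference CWR less LNCaP with ENZ no longer passed (adjusted p = 0.0859), and the others did. Differences with olaparib in VCaP hold the dim array. No biological explanation of the line differences was tested.

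Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each of the following the number of splits with as many genes, the real one included, was 1 except 3 in ENZ+OLA vs ENZ, VCaP. The real count and the highest of the others were ENZ vs DMSO, LNCaP 812 and 1, OLA vs DMSO, LNCaP 342 and 1, ENZ+OLA vs DMSO, LNCaP 2241 and 0, ENZ+OLA vs ENZ, LNCaP 412 and 1, ENZ+OLA vs OLA, LNCaP 1124 and 1, ENZ vs DMSO, VCaP 528 and 1, OLA vs DMSO, VCaP 13 and 4, ENZ+OLA vs DMSO, VCaP 1239 and 0, ENZ+OLA vs ENZ, VCaP 11 and 179, ENZ+OLA vs OLA, VCaP 1996 and 1582, ENZ vs DMSO, CWR 16 and 1, OLA vs DMSO, CWR 247 and 1, ENZ+OLA vs DMSO, CWR 935 and 2, ENZ+OLA vs ENZ, CWR 1539 and 2, ENZ+OLA vs OLA, CWR 216 and 1. Every split of ENZ+OLA vs OLA in VCaP holds the dim array, and 1 of them called 1582 genes. In ENZ+OLA vs ENZ, VCaP, a split called 179 without the dim array in either group, which points to a structure among those arrays.

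For departures from the sum, 100 regroupings of the 12 arrays of a line were drawn. In CWR 3 of 100 gave as many genes (real 110, highest other 123). In LNCaP 25 of 100 gave as many (real 3, highest other 568) and in VCaP 100 of 100 (real 0, highest other 1090). Regroupings with several times the real count point to a structure of the samples, such as arrays of the same treatment put together. For line differences, with treatment and DMSO arrays shuffled within lines, 1 of 100 draws gave as many genes with enzalutamide (real 590, highest other 439), 1 with olaparib (186, 156) and 2 with the combination (1470, 1514). Both shuffles undo the treatment effects. They cannot test departures from the sum or line differences, so an arbitrary grouping is not set aside for either.

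The 1996 calls between the combination and olaparib in VCaP were mostly higher (74.3%). Without the dim array, 21.1% of them kept call and direction, 52.2% of the calls were higher, and the median size of the change of the same genes went from 0.89 to 0.51. Leaving out another OLA array raised the count, to 4332 or 4888, and leaving out ENZ+OLA replicate 3 lowered it to 752. The tables argue against another cell line on that array, since its mean correlation with the other VCaP arrays was higher by 0.0902 than with the next line. A response to olaparib in the 2 other arrays stays open: VCaP gave 1.89% as many genes as LNCaP without the dim array, but 86.8% with array quality weights. Near-background signals on the dim array are a candidate explanation for part of these calls.

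The 110 genes off the sum in CWR were tested in 3 ways. Leaving out 1 of the 3 ENZ+OLA arrays left at least 50 genes, above 0.25 of the count, which argues against a single array of that group. Outside it, DMSO replicates 2 and 1 took the count to 34 and 439. 27.3% of the genes had no protein-coding entry, against 22.8% of all genes tested, so that ribosomal RNA carried into the label would not account for the other 80. A shift with base composition stays open: all 3 ENZ+OLA arrays lay beyond the other 9 CWR arrays in the mean of genes on GC-rich chromosomes (16, 17, 19 and 22) less that on AT-rich chromosomes (3, 4, 5 and 13), 0.068 to 0.12 against -0.029 to 0.051, permutation p = 0.00455, the smallest that 220 splits can give. The shift, 0.0867, is small beside falls of over 2, and treatment and a difference in RNA or labelling between groups cannot be parted by it. A response to the combination itself remains possible.

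Homologous recombination and Fanconi genes fell in 10 comparisons, in each of which the replication list fell too, but with an estimated correlation only 3 of the 10 passed. With each array's mean of 42 replication genes as a covariate, the list kept its call in 0 of the 10. Its mean went from between -0.35 and -0.13 (SD over members 0.25 to 0.43) to between 0.015 and 0.15 (SD 0.44 to 1.00) with 36 arrays, where the dim array sets much of the covariate. With 35 arrays it went to between -0.15 and -0.012 (SD 0.34 to 0.71), with 0 calls kept. In the fits with 36 arrays the mean of all genes went to between 0.13 and 0.32, and the list lay below it in all 10. The calls ended through a smaller mean and a wider spread, since the covariate moves with the treatments, so their loss decides nothing and a fall along with cell division stays open. For falls on adding olaparib, lower androgen-driven transcription is argued against, since the list fell with it in LNCaP (mean -0.18), where androgen-induced genes rose. That fall did not pass with an estimated correlation (adjusted p = 0.0971) and did with 35 arrays (0.0135). In ENZ+OLA vs ENZ, CWR, the list fell with both (mean -0.35, 0.0410 with the estimated one), beside -0.037 for androgen-induced genes. For falls with enzalutamide added, that cause stays open.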

How the results depend on the processing

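The 35 arrays and the array quality weights were chosen after the data were seen, the other alternatives before. Comparison counts below are genes at an adjusted p under 0.05. Except where a cause is given, the cause was not tested. Of 433 calls of named genes and 94 list calls, 419 of 433 and 94 of 94 kept call and direction with a trend and robust variance, 408 of 433 and 90 of 94 with no detection filter, 402 of 433 and 91 of 94 with the mean of the probes, 415 of 433 and 90 of 94 with the authors' values, 419 of 433 and 90 of 94 with 35 arrays, and 128 of 433 and 70 of 94 with median scaling.

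Median scaling moved most counts. LNCaP had 148 (39.2% higher against 52.0%) in ENZ vs DMSO, 31 (74.2% higher against 49.7%) in OLA vs DMSO, 395 (67.3% higher against 49.2%) in ENZ+OLA vs DMSO, 43 (74.4% higher against 43.9%) in ENZ+OLA vs ENZ, 238 in ENZ+OLA vs OLA, 0 genes off the sum. VCaP had 65 (83.1% higher against 61.9%) in ENZ vs DMSO, 2 in OLA vs DMSO, 40 in ENZ+OLA vs DMSO, 0 in ENZ+OLA vs ENZ, 54 (all higher against 74.3%) in ENZ+OLA vs OLA. CWR had 0 in ENZ vs DMSO, 10 (80.0% higher against 49.8%) in OLA vs DMSO, 48 (33.3% higher against 46.6%) in ENZ+OLA vs DMSO, 68 (63.2% higher against 45.6%) in ENZ+OLA vs ENZ, 30 (6.67% higher against 24.5%) in ENZ+OLA vs OLA, 2 genes off the sum. There were 94, 16 and 165 line differences with ENZ, OLA and ENZ+OLA, and 128 named calls. The array medians lie near background (121 to 191 against background modes of 114 to 173 on the 35 arrays), so that this scaling leaves the arrays' brightness unequal. The median of all genes under it was -0.72 in OLA vs DMSO and 0.67 in ENZ+OLA vs OLA, VCaP, against -0.096 and 0.10 with quantile normalization, and no more than 0.13 in size elsewhere. 10 genes called lower in ENZ+OLA vs OLA, VCaP had positive changes under it without passing, each below that median (CCNE2 0.11, PRIM1 0.46, E2F2 0.59, TYMS 0.61, CCNA2 0.38, CDK1 0.61, BIRC5 0.66, ME1 0.22, FASN 0.37, ACLY 0.55), and 4 lists changed test direction (G2/M and mitosis genes, OLA vs DMSO, VCaP -1.01, cholesterol synthesis genes, OLA vs DMSO, VCaP -1.10, G2/M and mitosis genes, ENZ+OLA vs OLA, VCaP 0.89, fatty acid synthesis genes, ENZ+OLA vs OLA, VCaP 0.74). Of the 4, the cholesterol list, which had not passed before (mean -0.028, test direction up), passed lower (adjusted p = 0.0289) and the others did not. Each of these comparisons holds the dim array.

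Quantile normalization without background correction moved these counts or their split. LNCaP had 7 genes off the sum. VCaP had 38 (23.7% higher against 7.69%) in OLA vs DMSO, 92 in ENZ+OLA vs ENZ. CWR had 34 (44.1% higher against 31.2%) in ENZ vs DMSO, 452 in OLA vs DMSO, 331 in ENZ+OLA vs OLA, 262 genes off the sum. There were 891 line differences with ENZ and 297 with OLA. The authors' values moved the following. LNCaP had 8 genes off the sum. VCaP had 38 (23.7% higher against 7.69%) in OLA vs DMSO, 74 in ENZ+OLA vs ENZ. CWR had 31 (45.2% higher against 31.2%) in ENZ vs DMSO, 434 in OLA vs DMSO, 331 in ENZ+OLA vs OLA, 251 genes off the sum. There were 291 line differences with OLA.

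With no detection filter no count moved by over 1.5 times. Probes detected on all arrays, fewer genes, moved these counts or their split. LNCaP had 517 in ENZ vs DMSO. VCaP had 416 (45.2% higher against 61.9%) in ENZ vs DMSO, 8 in OLA vs DMSO, 1238 (41.8% higher against 52.1%) in ENZ+OLA vs DMSO, 74 in ENZ+OLA vs ENZ, 709 (43.4% higher against 74.3%) in ENZ+OLA vs OLA. CWR had 5 in ENZ vs DMSO, 271 genes off the sum. Named calls came to 254, all of the 254 still tested. The immediate-early list in OLA vs DMSO, CWR kept a negative mean of -0.012, with the test direction turned up and without passing. The mean of a gene's probes moved 1 count. CWR had 25 in ENZ vs DMSO. BIRC5 in ENZ+OLA vs OLA, VCaP turned to 0.018 without passing. A trend with robust variance moved 3 counts. LNCaP had 5 genes off the sum. VCaP had 17 in ENZ+OLA vs ENZ. CWR had 9 in ENZ vs DMSO.

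Each cell line alone, with its own spread, moved these. LNCaP had 2304 in ENZ vs DMSO, 1306 in OLA vs DMSO, 4985 in ENZ+OLA vs DMSO, 1670 in ENZ+OLA vs ENZ, 2896 in ENZ+OLA vs OLA, 17 genes off the sum. VCaP had 66 in ENZ vs DMSO, 0 in OLA vs DMSO, 132 in ENZ+OLA vs DMSO, 0 in ENZ+OLA vs ENZ, 36 in ENZ+OLA vs OLA. CWR had 3 in ENZ vs DMSO, 55 genes off the sum. In LNCaP this leaves out the dim array and gives more calls, and in VCaP the dim array weighs more and few calls remain. 35 arrays moved these counts. LNCaP had 1254 in ENZ vs DMSO, 581 in OLA vs DMSO, 718 in ENZ+OLA vs ENZ, 1691 in ENZ+OLA vs OLA, 14 genes off the sum. VCaP had 1054 in ENZ vs DMSO, 2491 in ENZ+OLA vs DMSO, 196 in ENZ+OLA vs ENZ, 598 in ENZ+OLA vs OLA, 2 genes off the sum. CWR had 37 in ENZ vs DMSO, 601 in OLA vs DMSO, 1715 in ENZ+OLA vs DMSO, 2623 in ENZ+OLA vs ENZ, 509 in ENZ+OLA vs OLA, 404 genes off the sum. Line differences were 1174 with ENZ and 2690 with ENZ+OLA. Array quality weights gave the dim array a weight of 0.0354, against 0.204 to 3.22 for the others, the highest for VCaP OLA replicate 2. The estimate of the weights stopped before convergence. They moved these. LNCaP had 2727 in ENZ vs DMSO, 1694 in OLA vs DMSO, 5199 in ENZ+OLA vs DMSO, 1847 in ENZ+OLA vs ENZ, 2841 in ENZ+OLA vs OLA, 56 genes off the sum. VCaP had 2198 in ENZ vs DMSO, 1471 in OLA vs DMSO, 3 in ENZ+OLA vs ENZ, 489 in ENZ+OLA vs OLA, 4 genes off the sum. CWR had 61 in ENZ vs DMSO, 628 in OLA vs DMSO, 2257 in ENZ+OLA vs DMSO, 4037 in ENZ+OLA vs ENZ, 1128 in ENZ+OLA vs OLA, 710 genes off the sum. There were 2215, 1709 and 3592 line differences with ENZ, OLA and ENZ+OLA.

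The replicate numbers do not pair the arrays: residuals of arrays with the same number correlated at a median of -0.015, 5.60e-04 and 0.00804 in LNCaP, VCaP and CWR, and 0, 7 and 3 of 12 arrays correlated best with their own number. The replicate block gave these counts. LNCaP had 759 in ENZ vs DMSO, 304 in OLA vs DMSO, 2137 in ENZ+OLA vs DMSO, 366 in ENZ+OLA vs ENZ, 1076 in ENZ+OLA vs OLA, 1 genes off the sum. VCaP had 443 in ENZ vs DMSO, 24 in OLA vs DMSO, 1148 in ENZ+OLA vs DMSO, 6 in ENZ+OLA vs ENZ, 2064 in ENZ+OLA vs OLA, 0 genes off the sum. CWR had 9 in ENZ vs DMSO, 217 in OLA vs DMSO, 822 in ENZ+OLA vs DMSO, 1363 in ENZ+OLA vs ENZ, 162 in ENZ+OLA vs OLA, 74 genes off the sum. There were 497, 152 and 1339 line differences with ENZ, OLA and ENZ+OLA.

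Leaving out each array in turn gave these ranges. LNCaP had 591 to 626 in ENZ vs DMSO, 186 to 221 in OLA vs DMSO, 1604 to 1761 in ENZ+OLA vs DMSO, 268 to 323 in ENZ+OLA vs ENZ, 842 to 899 in ENZ+OLA vs OLA, 1 to 4 genes off the sum. VCaP had 278 to 374 in ENZ vs DMSO, 1 to 4176 in OLA vs DMSO, 702 to 1727 in ENZ+OLA vs DMSO, 0 to 432 in ENZ+OLA vs ENZ, 598 to 4888 in ENZ+OLA vs OLA, 0 to 150 genes off the sum. CWR had 5 to 173 in ENZ vs DMSO, 142 to 453 in OLA vs DMSO, 554 to 930 in ENZ+OLA vs DMSO, 869 to 1158 in ENZ+OLA vs ENZ, 120 to 148 in ENZ+OLA vs OLA, 34 to 439 genes off the sum. Line differences were 459 to 712 with ENZ, 102 to 1372 with OLA and 1121 to 1793 with ENZ+OLA. List calls ranged from 91 to 100 and named calls from 399 to 430, within 1.5 times.

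Leaving out these arrays moved a count by over 1.5 times, to the value given. OLA vs DMSO, LNCaP: DMSO 1 186, DMSO 2 206, DMSO 3 221, OLA 1 196, OLA 2 211, OLA 3 200. ENZ+OLA vs ENZ, LNCaP: ENZ 3 268, ENZ+OLA 3 270. ENZ vs DMSO, VCaP: DMSO 1 297, DMSO 2 278, DMSO 3 299, ENZ 2 326, ENZ 3 304. OLA vs DMSO, VCaP: DMSO 1 1, DMSO 2 7, DMSO 3 2, OLA 2 3348, OLA 3 4176. ENZ+OLA vs DMSO, VCaP: DMSO 1 702, DMSO 2 759, DMSO 3 784. ENZ+OLA vs ENZ, VCaP: ENZ 1 0, ENZ 2 3, ENZ 3 3, ENZ+OLA 1 432, ENZ+OLA 2 0, ENZ+OLA 3 57. ENZ+OLA vs OLA, VCaP: OLA 1 598, OLA 2 4332, OLA 3 4888, ENZ+OLA 3 752. ENZ vs DMSO, CWR: DMSO 1 173, DMSO 2 7, DMSO 3 5, ENZ 2 10, ENZ 3 9. OLA vs DMSO, CWR: DMSO 1 453, DMSO 2 142, OLA 1 147, OLA 2 145, OLA 3 150. ENZ+OLA vs DMSO, CWR: ENZ+OLA 1 554, ENZ+OLA 3 556. ENZ+OLA vs ENZ, CWR: ENZ 1 913, ENZ 2 869, ENZ+OLA 1 869, ENZ+OLA 3 965. ENZ+OLA vs OLA, CWR: OLA 1 137, OLA 2 120, OLA 3 130, ENZ+OLA 1 133, ENZ+OLA 3 138. Off the sum in LNCaP: DMSO 2 1, ENZ 1 1, ENZ 3 1, OLA 1 1, OLA 2 1, ENZ+OLA 1 1. Off the sum in VCaP: OLA 1 2, OLA 2 77, OLA 3 150, ENZ+OLA 1 18, ENZ+OLA 3 3. Off the sum in CWR: DMSO 1 439, DMSO 2 34, ENZ 2 50, ENZ 3 64, OLA 1 65, OLA 2 41, OLA 3 49, ENZ+OLA 1 61, ENZ+OLA 3 50. Line differences with OLA: VCaP DMSO 1 103, VCaP DMSO 2 114, VCaP DMSO 3 102, VCaP OLA 3 1372. With VCaP OLA 2 or 3 left out, the dim array makes up 1 of 2 arrays of its group, and the counts rise. Fewer arrays in a group also give less power by construction.

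Signal over background limits the rest, since genes near background are compressed toward no change.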

Other observations

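The hypoxia-response test was chosen after the gene results were seen, and its list was written before it was run. Genes that fell most with olaparib in LNCaP included PLOD2, STC1, LOX and TMEM45A, which led to the hypothesis of a fall of hypoxia-response genes as a group. A list of 31 other such genes, 29 of them measured, fell by 0.36 on the log2 scale on average (SD 0.28) in OLA vs DMSO, LNCaP, with 2 members past the threshold, PFKFB3 (-0.99, SE 0.14) and PFKFB4 (-0.96, SE 0.22), and 0 the other way (limma). The camera p was 1.18e-10, and 0.00514 with an estimated correlation of 0.165. Olaparib may thus have lowered this group in LNCaP, or the cultures may have differed in oxygen or density, which no value here tests.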
